A study of Zea mays with 4 samples.

How the data were processed

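Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wild-type maize endosperm at 15 days after pollination, per the labels. ChIP-seq recovers the DNA fragments that are crosslinked to a protein and maps them to the genome. One antibody was raised against ZmbZIP22, a transcription factor of the basic leucine zipper (bZIP) class, and nonspecific immunoglobulin (IgG) served as the antibody control. There were 4 libraries, an anti-ZmbZIP22 library and an IgG library in each of 2 replicates. The labels do not say whether the replicates came from separate plants or pools of kernels.

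Alignment with Bowtie2 (version not given in the sources used here) and peak calling with MACS2 2.0.10 are listed in the submitters' processing notes. The genome build, the calling threshold and any later filter are not given in the sources used here. Each anti-ZmbZIP22 library had a peak table and a BED file. An IgG library could enter only through the comparison the peak caller made, and which control each call used was not established here. The headings of columns 7 and 9 of the tables held a spreadsheet error. These columns were read as −log10 p and −log10 q from the standard column order of a MACS2 table. The −log10 p column equalled the score of the BED file throughout and exceeded the −log10 q column in every peak.

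The deposited pileup is a signal value, the number of fragments stacked at the summit after the caller has scaled the larger library down. The deposited fold enrichment is the ratio of that pileup to the local background, and the deposited −log10 p and −log10 q values measure the same excess before and after multiple-testing correction. All of these are the authors' own values for each peak and came without an error. Both end positions belong to the peak, because peak length equalled end minus start plus 1 in every row. The BED file held the same starts, so whether positions are counted from 1 was not settled. Library depth is unknown here, so no read-based interval was computed. Intervals given below are exact 95% (Clopper-Pearson) intervals on shares of peaks and cover counting error only.

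A peak was called shared when it overlapped a peak of the other replicate by at least 1 bp. The number shared was compared with 10000 random placements of the replicate 2 peaks on their own chromosomes, one-sided, with each chromosome taken to end at the last peak of either list. Agreement of fold enrichment over shared peaks was measured with Pearson's r and Spearman's rho, with 100000 permutations and a bootstrap interval. Medians of shared and unshared peaks were compared with a two-sided permutation test of 100000 resamples. Peaks per chromosome were compared with the span of each chromosome by a chi-square statistic whose p came from 100000 multinomial draws. The design called for true chromosome lengths there, and the last peak end stood in for them.

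Peaks with a summit of the other list within 500 bp are called partnered and the others lone. Fold enrichment of a shared peak was set against the peak that overlapped it most. For summit offsets, the implied background and agreement over pairs by summit distance, partnered peaks were matched in order of position on each chromosome. All such matches lay within 500 bp, but a match was not always the nearest summit. A background was computed for each peak from the pileup and the fold enrichment, with a pseudocount of 1. The division into partnered and lone peaks was chosen after the data had been examined. So were the settings that use it, the test of summit offsets against an even spread over 300 bp to each side (10000 simulations), the step of the pileup values, the implied background, the comparison of p with q (by linear reading between p-values, and by whether q lay between those of its neighbours in p), the count of lone intervals once each, the tests between partnered and lone peaks, and the counts in 10 Mb windows. The overlap, agreement, shared-against-unshared and chromosome comparisons, their first alternatives and the naming rule were fixed before the data were examined. The alternatives were a stricter list (upper 50% by −log10 q), an overlap of 50% of both peaks, summits within 200 bp, pileup or −log10 q in place of fold enrichment, and each list alone.

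The naming rule took the 15 shared peaks with the highest smaller-of-the-replicates fold enrichment that lie near a gene, members of the gene lists, and 4 genes chosen in advance. It also took the 3 peaks with the highest fold enrichment in each list that have no partner in the other. Without an annotation of the build it provided for naming by position, so the parts that need genes were left out and the 15 peaks were taken without regard to genes, each interval once.

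On simulated lists of 1961 and 1791 peaks, the overlap count recovered 500 of 500 planted shared peaks. When 10% of 1550 simulated pairs were placed at a common site with a narrow spread of summit offsets, the even-spread test gave p = 0.00799 (n = 1550, by simulation). This was a single draw, and the power of the test for wider summit scatter was not measured. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

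The planned comparisons with promoters, with sequence motifs, with short sequence words and with gene lists (storage proteins, starch and sugar metabolism, endosperm regulators, bZIP factors, folding in the endoplasmic reticulum, heat shock, cytosolic ribosome, and markers of embryo, aleurone, basal transfer layer and leaf) were not made. The files name no genes, the build of their coordinates is not stated, and the gene table at hand was of a named assembly that could not be matched to it. Peaks are therefore named by position only.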

Results

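The binding of ZmbZIP22 to the genome was mapped in maize endosperm, the starch- and protein-storing tissue of the kernel, at 15 days after pollination. ZmbZIP22 is a bZIP transcription factor known for its action on a gene of the zeins, the storage proteins of the endosperm. The data were 2 lists of peaks, one per replicate of the anti-ZmbZIP22 immunoprecipitation, each carrying the summit, height, fold enrichment and significance given by the authors' peak caller. The 2 IgG libraries were the antibody control, and no IgG values were analysed here. Which control library each call used was not established. Whether the 2 replicates came from separate plants is not stated in the labels, so p-values below describe these lists and not the spread between plants.

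Replicate 1 held 1961 peaks and replicate 2 held 1791, all on chromosomes 1 to 10. The peaks were narrow, with a median length of 341 bp in replicate 1 and 397 bp in replicate 2. The peaks covered 740866 bp in replicate 1 and 733089 bp in replicate 2. The median fold enrichment was 4.54 in replicate 1 (quartiles 3.63 and 8.87) and 8.64 in replicate 2 (quartiles 5.73 and 19.0). The tallest peak of each list was picked out after its values were seen. That in the replicate 1 list lay on chromosome 2 at 78510496 to 78511303, with a pileup of 5147 and 81.3-fold enrichment. That in the replicate 2 list lay on chromosome 6 at 169290013 to 169290823, with a pileup of 670 and 81.9-fold enrichment. Neither had a summit of the other list within 500 bp, and such peaks were not shown to come from the library of the list that holds them. Some entries repeated another in full, 40 in replicate 1 and 15 in replicate 2. The lists held 1867 and 1775 distinct intervals, of which 0 and 30 overlapped an interval that came earlier on the chromosome. Further entries of replicate 1 shared an interval with another but had a different summit, and were counted as separate peaks throughout.

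The first comparison asked which peaks were found in both replicates. Of the replicate 1 peaks, 1494 overlapped a replicate 2 peak, or 76.2% (exact 95% interval 74.2% to 78.1%). Of the replicate 2 peaks, 1491 overlapped a replicate 1 peak, or 83.2% (81.4% to 85.0%). Random placement of the replicate 2 peaks gave 1.94 shared peaks on average and 11 at most in 10000 placements. The one-sided p over the n = 1961 peaks was 1.0e-04, the smallest that 10000 placements can give. With at least 50% of both peaks required to overlap, 731 of the replicate 1 peaks were shared, and between the upper 50% of each list by −log10 q, 248 of 981 were, or 25.3%. Those 981 include 411 with no summit of the other list within 500 bp, which lowers the share. They account for only part of the fall. Many partnered peaks also lost their match because the partner was in the lower 50% of the other list. The lowest −log10 q of these 411 was 59.4, against a list median of 7.02. Each list fell into 2 classes by distance to the other: 1550 peaks had a summit of the other list within 497 bp, and no other peak had one closer than 4278 bp. Such a break could arise if the lists had been selected on closeness to each other, which was not established. An excess of overlap over placement would then be fixed in advance. The overlap and its p therefore describe these lists and were not taken as evidence or as a rate of replication.

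**Figure D1:**
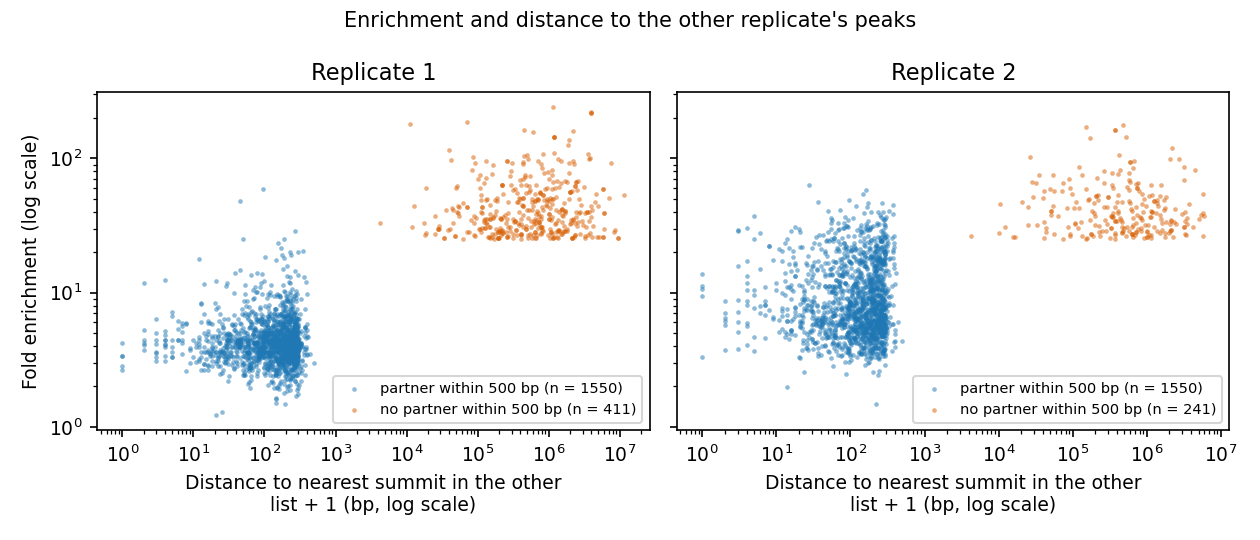
Fold enrichment (log axis) of every peak against the distance from its summit to the nearest summit in the other replicate (bp plus 1, log axis), with replicate 1 on the left and replicate 2 on the right. The 1550 partnered peaks of each list lie within 497 bp, and the 411 and 241 lone peaks lie beyond 4278 bp, all at a fold enrichment above 25.

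Positions of shared peaks are given as the replicate 1 interval, and the replicate 2 value belongs to the replicate 2 peak that overlaps it. The peaks were ranked by the smaller of the replicates' fold enrichments, so high values in both follow from the choice. Overlap was not taken to show a common binding site. Among shared peaks, the first by this rank was on chromosome 1 at 58256174 to 58256861. It had 59.6-fold enrichment in replicate 1 and 30.7-fold in replicate 2. The second was on chromosome 7 at 46497117 to 46497558, with values of 24.99 and 24.6. A shared peak on chromosome 1 at 90962998 to 90963532 had 48.4-fold enrichment in replicate 1 and 20.6-fold in replicate 2. Another on that chromosome, at 90334105 to 90334480, had 23.2 and 16.8. Chromosome 1 also held shared peaks at 57557753 to 57558188 (19.96-fold and 21.5-fold) and at 107303766 to 107304146 (13.6-fold and 20.4-fold). In the first of these, the replicate 2 summit lay outside the replicate 1 interval, 228 bp from the replicate 1 summit. On chromosome 6, the peak at 141268977 to 141269515 reached 19.1-fold and 26.3-fold, and the peak at 133165170 to 133165569 reached 15.8-fold and 14.1-fold. On chromosome 5, the replicate 1 peaks at 204689095 to 204689502 and 210459277 to 210459703 had 13.01-fold and 11.98-fold enrichment, and the replicate 2 peaks that overlap them had 25.4-fold and 26.5-fold. The replicate 2 summits lay outside these replicate 1 intervals, 361 and 387 bp from the replicate 1 summits. Another shared peak of chromosome 5, at 177873884 to 177874260, had 14.7-fold and 11.2-fold enrichment.

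The remaining named shared peaks were on chromosome 1, at 156332344 to 156332766, 51410542 to 51411024, 19814772 to 19815157 and 107231017 to 107231501. Their fold enrichment ran from 11.1 to 12.5 in replicate 1 and from 25.02 to 31.2 in replicate 2. Of the 15 named shared peaks, 9 lay on chromosome 1, 3 on chromosome 5, 2 on chromosome 6 and 1 on chromosome 7. Only 3 of the 15 had summits within 50 bp of each other in the replicates. The summits of the chromosome 1 peak at 156332344 were 3 bp apart, and those of the chromosome 5 peak at 210459277 were 387 bp apart.

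The second comparison asked whether a site that was strongly enriched in one replicate was strongly enriched in the other. No rank relation was detected over the shared peaks as a whole. Across 1494 overlapping peaks, Spearman's rho of fold enrichment was 0.0068 (bootstrap 95% interval −0.0452 to 0.0583, two-sided permutation p = 0.792). Pearson's r was 0.0543 (permutation p = 0.0357). It fell to 0.0162 without the 2 pairs whose replicate 1 fold enrichment lay farthest from the replicate 1 median, so that value rested largely on those 2 pairs. These are correlations across peaks of 2 libraries, and peaks are not independent replicates. Pileup height gave a rho of 0.0126 (permutation p = 0.626). The local background implied by pileup and fold enrichment did not track between partners either, with a rho of −0.0109 over 1550 pairs (permutation p = 0.666).

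Summit positions of partners were compared next. The median distance between partner summits was 149 bp, against median peak lengths of 312 and 373 bp among partnered peaks. Of the 1550 pairs, 1495 had summits within 300 bp, and 277 of these, or 18.5% (exact 95% interval 16.6% to 20.6%), were within 50 bp. An even spread over 300 bp to each side gives 16.8%. The 12 bins of 50 bp within that range held between 108 and 138 pairs each, and the offsets did not differ detectably from an even spread (p = 0.653 by simulation, n = 1495). Beyond 300 bp the number dropped to 55 pairs.

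**Figure D2:**
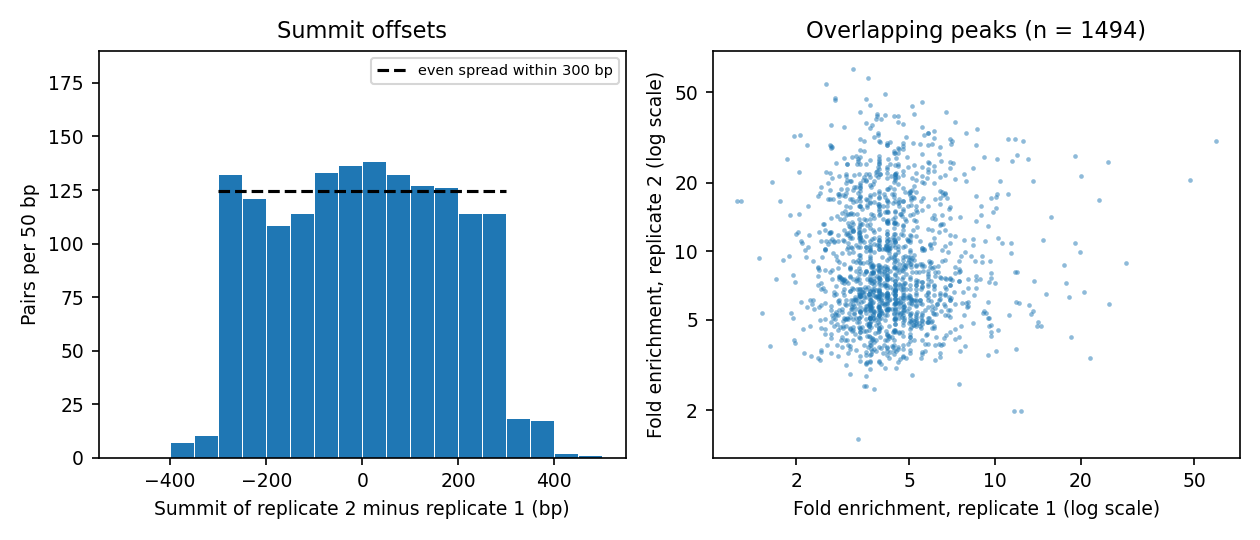
Left, the number of partner pairs per 50 bp of summit offset (replicate 2 minus replicate 1, in bp), with a dashed line for an even spread of the 1495 pairs within 300 bp. Right, fold enrichment in replicate 2 against replicate 1 (log axes) for the 1494 overlapping peaks, where rho was 0.0068.

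The third comparison set peaks found in both lists against those found in one. In the lists as given, the most enriched peaks were unshared. Most unshared peaks were lone, and no lone peak had a fold enrichment under 25.02. The differences and p-values below therefore describe the composition of the lists, not whether unshared binding was stronger. In replicate 1 the median fold enrichment was 4.18 for 1494 shared peaks and 35.2 for 467 unshared peaks, a difference of −30.99 (two-sided permutation p = 1.0e-05, the smallest that 100000 resamples can give). In replicate 2 the medians were 7.66 for 1491 shared and 33.6 for 300 unshared peaks, a difference of −25.89 (permutation p = 1.0e-05). With 50% of both peaks required to overlap, the differences shrank to −1.10 and −1.97 (permutation p = 1.0e-05 and 1.1e-04). The strongest unshared peaks in the replicate 1 list were on chromosome 2 at 199110116 to 199110859 (240-fold), chromosome 8 at 74837731 to 74838513 (223-fold) and chromosome 7 at 64601632 to 64602322 (217-fold). Those in the replicate 2 list were on chromosome 3 at 28612207 to 28613356 (177-fold), and on chromosome 1 at 90560204 to 90561061 (171-fold) and 286684682 to 286685425 (163-fold). The nearest summits of the other list were between 150558 and 4002368 bp away. All are lone peaks, and the list that holds such a peak was not shown to be the library it came from.

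The difference came from the lone peaks. All 411 lone peaks of replicate 1 and all 241 of replicate 2 had a fold enrichment of at least 25.02, whereas 0.258% of the 1550 partnered peaks of replicate 1 and 6.52% of those of replicate 2 reached 25. Without the lone peaks, the unshared peaks of replicate 1 had a median of 3.94 (n = 56) and those of replicate 2 a median of 5.65 (n = 59), both below the medians of the shared peaks (differences of 0.24, permutation p = 0.346, and 2.02, permutation p = 0.0243). The lone peaks of replicate 1 and replicate 2 had a median fold enrichment of 37.97 and 37.88 (highest 240 and 177) and a median length of 572 and 584 bp. Since both sets begin at the same fold enrichment, their medians were not compared.

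The lone peaks also differed from the partnered peaks of their own list in the relation of q to p, and in replicate 1 in the scale of the pileup. In replicate 1, each of the 1550 partnered peaks had a pileup at a multiple of 0.87574 (within 0.01), with a median of 23 fragments, while all 411 lone peaks had pileups that were whole numbers exactly as deposited, of which 2 fell at such a multiple. In replicate 2 the pileup showed no such difference, with whole numbers in all 1550 partnered and all 241 lone peaks. Among p-values found in lone peaks of both lists there were 35, and all 35 carried the same q in both, with p and q equal in every deposited decimal. Across 212 p-values of lone replicate 2 peaks, the gap between −log10 p and −log10 q differed from that of lone replicate 1 peaks by 0.00031 at the median and 0.0037 at most. No p was found in both lone and partnered peaks of a list, so their gaps were compared by reading between neighbouring p-values, and differed by a median of 2.88 in replicate 1 and 1.39 in replicate 2. Without reading between points, the q of lone peaks was more significant than that of both neighbouring partnered peaks at 59 of 261 p-values in replicate 1 and 142 of 186 in replicate 2. Between the lone peaks of the lists this occurred at 0 of 212. The lowest implied background was 0.868 among the lone peaks of either list, 2.17 among partnered peaks of replicate 1 and 1.35 among those of replicate 2.

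**Figure D3:**
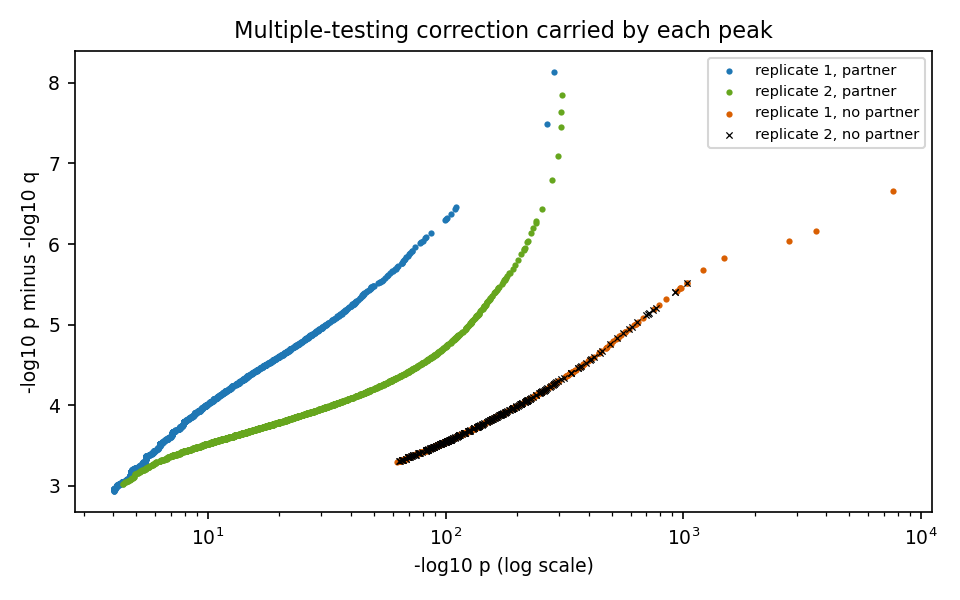
The difference between −log10 p and −log10 q of each peak (vertical axis) against its −log10 p (horizontal axis, log scale), for partnered and lone peaks of each replicate. The partnered peaks of replicate 1 and replicate 2 follow separate curves, and the lone peaks of both lists follow 1 further curve, differing from each other by at most 0.0037.

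The last comparison asked how the listed peaks were distributed over the chromosomes. Shared peaks were concentrated on chromosomes 1, 2 and 6 and sparse on chromosomes 3, 4, 8, 9 and 10. Since no relation of height by rank or of summit position was detected across the partners as a set, these shares describe overlapping entries of the lists and were not taken as the distribution of common binding sites. Chromosome 1 held 536 of the 1494 shared peaks, or 35.9% (exact 95% interval 33.4% to 38.4%), against 14.7% of the span. Chromosome 6 held 14.1% (12.3% to 15.9%) against 8.26%, and chromosome 2 held 15.3% (13.5% to 17.2%) against 11.6%. Chromosome 4 held 3.41% (2.55% to 4.46%) against 11.7%, and chromosome 8 held 2.61% (1.86% to 3.55%) against 8.55%. The span of a chromosome here ends at its last peak, since its length in the build of the files was not known. The counts differed from the spans more than independent draws gave (chi-square 812.4, p = 1.0e-05 by multinomial draws, the smallest that 100000 can give). The draws and the exact intervals treat peaks as independent, but partnered peaks clustered along the chromosomes, so both understate the uncertainty. The same holds for the test of partnered against lone peaks below.

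The lone peaks were not distributed in this way. Chromosome 1 held 109 of the 652 lone entries of both lists, or 16.7% (13.9% to 19.8%), and the counts over all 10 chromosomes did not differ detectably from the spans (chi-square 5.43, p = 0.794 by multinomial draws). All entries repeated in full were lone peaks, while partnered entries of replicate 1 that share an interval differ in summit. With each of the 596 distinct lone intervals counted once, the share on chromosome 1 was 16.6% (chi-square 5.39, p = 0.799 by multinomial draws). Partnered and lone peaks differed from each other in distribution in a test that needs no chromosome length (chi-square 194.9, or 183.7 with each interval once, permutation p = 1.0e-05 for both). The lone peaks of replicate 1 and of replicate 2 did not differ detectably (chi-square 2.91, permutation p = 0.968).

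**Figure D4:**
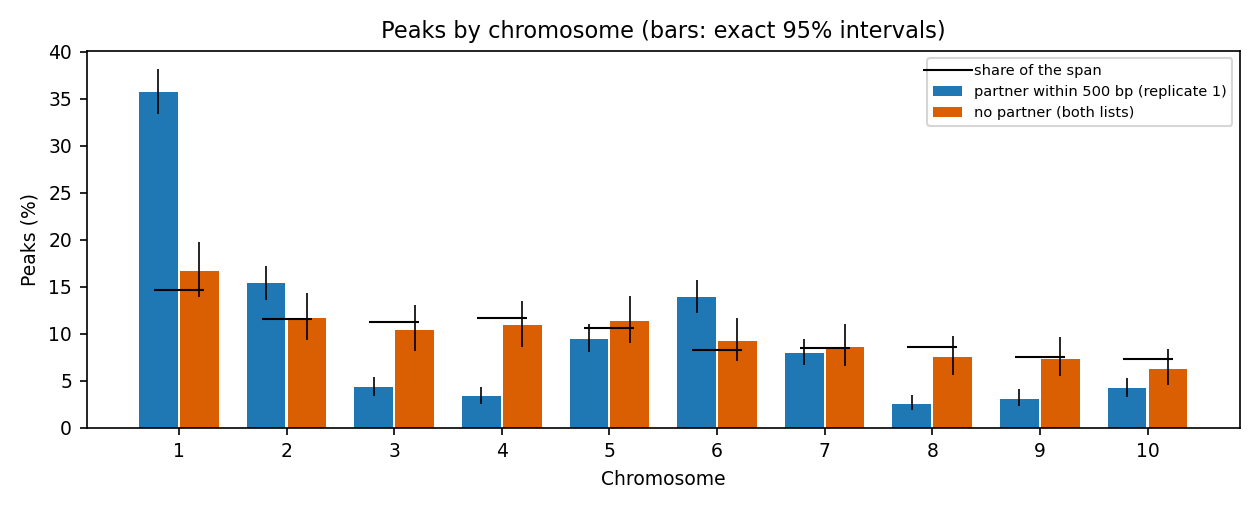
Share of peaks (%) on each of the 10 chromosomes for partnered peaks of replicate 1 and lone peaks of both lists, with exact 95% intervals, and the chromosome's share of the total span as a horizontal mark. Chromosome 1 holds 35.7% of partnered and 16.7% of lone peaks, against 14.7% of the span.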

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

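The alternatives that left out repeated entries, lone peaks or partnered peaks, used all pairs within 500 bp, or took the upper 50% of pairs were chosen after seeing the data. The upper 50% of each list by −log10 q held 981 and 896 peaks by construction. Shared peaks numbered 731 when 50% of both peaks had to overlap and 248 between those stricter lists, against at most 7 by placement. The stricter lists hold every lone peak, which lowers the share found in both. So does the loss of partnered peaks whose partner fell in the lower 50% of the other list. All peaks lay on the 10 chromosomes, so a restriction to these changed no count. The rank agreement stayed near 0 in the other 4 alternatives, with a highest rho of 0.0342 (permutation p = 0.337). Pearson's r rose to 0.086 with summits within 200 bp (permutation p = 0.0116), 0.0616 over all pairs (permutation p = 0.0181) and 0.1 in the upper 50% of pairs (permutation p = 0.00829). Without the 2 pairs farthest from the median in replicate 1, it was 0.0367, 0.0253 and 0.0468, where it was not tested. The excess of unshared over shared fold enrichment kept its direction with −log10 q and, much reduced, with the 50% overlap (−1.10 in replicate 1 and −1.97 in replicate 2). It reversed when the lone peaks were left out, to 0.24 in replicate 1 (permutation p = 0.346) and 2.02 in replicate 2 (permutation p = 0.0243), as it rests on those peaks. The share on chromosome 1 was 31.7% to 33.2% in the single lists, past the threshold in both. It fell to 16.7% among lone entries, or 16.6% with each interval once, no longer past the threshold. No paired analysis was possible because the IgG libraries have no values of their own here. Leaving out a replicate leaves no second list for the overlap and agreement comparisons. Placement near genes, and the alternatives of the promoter, motif, word and gene-list comparisons, were not run for want of a matching genome. The lowest partnered peak of replicate 1 rested on 11 fragments, which limits how precisely its summit can be placed.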

Other observations

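The window counts and the tests of this part were chosen after the results had been seen, except that rho was a planned measure. Partnered peaks were unevenly spread along the chromosomes. In windows of 10 Mb, the median window held 3 partnered peaks, yet the window at 100 to 110 Mb of chromosome 1 held 60 and that at 90 to 100 Mb held 58. Chromosome 5 held 48 in the window at 200 to 210 Mb and 42 in the last window, from 210 Mb on, and chromosome 6 held 47 between 10 and 20 Mb. The 10 fullest of 209 windows held 28.0% of the partnered peaks, and 28 windows held none. The 652 lone entries, repeats included, also had a median of 3 per window, but no window held more than 11, and their own 10 fullest windows held 14.4%.

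As a set, partner peaks showed no detectable relation of height by rank or of summit position. Were they the same binding sites measured in both libraries, summits would gather near an offset of 0, but 18.5% lay within 50 bp (upper limit 20.6%) against 16.8% for an even spread, and the upper limit of rho was 0.0702 over all 1550 pairs and 0.1035 in the upper 50% by the smaller fold enrichment. Where the summits of a common site lie within 50 bp of each other, the upper limit leaves 4.55% of the 1495 pairs within 300 bp for such gathering. In that upper 50% it leaves 6.6% (19.3% within 50 bp, upper limit 22.3%). For sites of that kind, this argues against common sites as the source of most pairs, and against values attached to the wrong peaks with positions intact. Common sites with summits farther apart are not bounded by these values, and partnered peaks of replicate 1 rested on a median of 23 fragments. A candidate explanation left open is that unrelated peaks of much longer lists met by coincidence. That would give evenly spread offsets. Coincidence alone would not leave the drop in pairs beyond 300 bp, or the break in distance between 497 and 4278 bp. The account therefore also needs a selection of peaks by distance to the other list, which was not tested. The offsets did not differ detectably from an even spread (p = 0.653 by simulation, n = 1495), which does not establish it. Such lists would need many significant peaks, as the median −log10 q of partnered peaks was 4.80 in replicate 1 and 15.3 in replicate 2. Placement of the partnered peaks alone gave 1.35 shared peaks on average. Whether longer lists existed was not tested, and no other origin of evenly spread offsets was tested.

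The most enriched peaks had no partner. Binding that differed between the endosperm samples, each called in its own run, would give lone peaks the same q at the same p as the partnered peaks of their list, yet read between neighbouring p-values, as none were equal, the values differed by a median of 1.39 log10 units in replicate 2 and 2.88 in replicate 1. The q also lay outside that of both neighbouring partnered peaks at 142 of 186 and 59 of 261 p-values, which 1 run for each list forbids, so this argues against that account. The lone peaks of both lists may instead come from 1 calling run, since 35 of 35 p-values found in both carried the same q, and a filter that kept partnered peaks, and others only above a fold enrichment of 25, could also have shaped the lists, as the lowest lone value was 25.02. Which libraries such a run used stays open, so these values do not assign the lone peaks to a replicate.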
